A study of Mus musculus with 8 samples.

How the data were processed

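Each of the 8 samples was total RNA from the abdominal white adipose tissue of adult mice, pooled in equal amounts from 5 mice. The design holds 4 groups of sex and genotype with 2 pools each: wild type males, wild type females, rsl males and rsl females. Per the labels, biotinylated cRNA was prepared from 400 ng of RNA with a 3' in vitro transcription kit and hybridized to Affymetrix Mouse Genome 430 2.0 PM arrays. The deposited values are log2 signals per probe set, which the authors summarised and normalized between arrays with RMA (robust multi-array average), version not stated. The labels give a source of liver RNA in one field and white adipose tissue in another, and the series design names adipose tissue.

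A separate deposited table of the authors gave the other unit, annotation text for each probe set (gene symbol, representative accession and gene title), and also held 8 columns of values whose headings match no label of a sample. Those 8 columns were not used. Of the 45141 deposited probe sets, 104 controls were set aside and 45037 were tested. Gene names were brought up to date through the RefSeq gene table of the assembly GRCm38.p6. The representative accession named 34512 probe sets, the symbol or a synonym 1097, and the deposited symbol alone 2743, which left 15 probe sets with several genes and 6670 with none. A total of 38352 probe sets named 20737 genes, and 3090 deposited symbols changed. A gene was represented by its probe set with the highest mean over all arrays.

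Arrays give no read depth, and the precision rests on the number of arrays. The background of each array was taken as the highest of 22 non-specific control probe sets with GC counts from 3 to 24, and the control with GC count 25 was left out after its values were seen. Where every array of the dimmer group, or in the average of either sex of the dimmer strain, lay at or below this bound, the difference was computed against the bound and is given as at least that many fold. Control genes with probe sets at the 3' and 5' ends served as a check of RNA integrity.

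Linear models were fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per group, all 8 arrays, empirical Bayes moderation with a constant prior variance, and no filter on dim probe sets. The model has 4 residual and 3 prior degrees of freedom. The 6 contrasts were rsl minus wild type in males, in females and averaged over sex, male minus female in wild type and in rsl, and the interaction (the genotype difference in males minus that in females). P-values are two-sided and Benjamini-Hochberg adjusted over the probe sets of a contrast, with a threshold of 0.05. Errors are the moderated standard errors (SE) of the model or the SD of the pools, 2 in a group or 4 of a strain in the average. The p-values measure only the spread between these pools, since mice within a pool are not resolved. Replicate numbers were checked as pairs of arrays. Correlations across probe sets of the deviations from the group mean ran from -0.048 to 0.115, except for 0.346 between wild type and rsl males. The numbers were not used to pair the arrays in the main model.

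Before the data were examined, the design, the alternative settings, the rule for named genes and 30 gene lists were fixed. The rule names, for each contrast, up to 12 genes with the largest rise and 12 with the largest fall among those past the threshold whose groups do not overlap, all zinc finger and sex chromosome genes of the lists, list members past the threshold, and up to 4 members with the smallest p of a described list. The lists cover the zinc finger cluster around Rsl1, liver targets of the Rsl genes, sex chromosome genes, lipid and energy metabolism, hormones, clock and early response genes, positional genes, and markers of adipocytes, immune cells and other tissues. They hold 541 members, of which 506 were measured. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the 30 lists of a contrast. Counts of list members are given over all genes tested and adjusted over the list alone. Chromosomes were compared with a two-sided Fisher's exact test over the genes with a chromosome. Shared calls were set against the product of the counts divided by the probe sets tested.

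The procedure was tested on simulated data with the spread of each group and 100 probe sets changed at each size. The noise was drawn independently for each probe set, so correlation between genes was not simulated. In males 88% of changes of 1 log2 unit and 97% of changes of 2 units were recovered, with 100 false calls among the 45037 probe sets. In females 86% and 97% were recovered with 0 false calls, and for the average 97% and 98% with 16 false calls. Alternatives were a fit of only the 2 groups compared, the replicate number as a block, an intensity trend, the brighter probe sets, quantile normalization, median centring, gene means, array weights, and each array left out in turn. Added after seeing the data were fits without the male pools that stood apart, without genes that differed between pools of a male group, and the chromosome test on genes called in both sexes.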

Results

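The arrays measured RNA in the white adipose tissue of adult mice with and without functional Regulator of sex-limitation (Rsl) genes. The wild type strain was B10.D2, and the rsl strain was B10.D2.PL, which is homozygous for the rsl alleles. Rsl genes code for Krüppel-associated box (KRAB) zinc finger proteins, a family of transcriptional repressors known from the liver, where they restrain genes with sex-biased expression. Each of the 4 groups (wild type males, wild type females, rsl males, rsl females) had 2 arrays, each of RNA pooled from 5 mice, and the sources used here do not say whether the pools of a group shared mice. Median signals lay between 4.54 and 4.58 on the log2 scale, and 62.9% to 71.0% of probe sets were above the array's non-specific background.

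Adipocyte transcripts were bright in every pool, and the male pools also held transcripts of the reproductive tract. The 20 measured adipocyte genes averaged 11.30 and 11.48 in the wild type male pools, 10.63 and 11.35 in the rsl male pools, and 11.31 to 11.47 in the 4 female pools. The 12 measured epididymis genes averaged 12.09 and 11.50 in the rsl male pools, 7.003 and 5.37 in the wild type male pools, and 3.98 to 4.16 in the female pools. The 12 testis genes averaged 6.50 and 6.18 in wild type males, 6.22 and 5.08 in rsl males, and 4.04 to 4.08 in females. The 14 skeletal muscle genes averaged 4.73 to 4.86 in the male pools, 7.86 and 7.57 in wild type females, and 7.38 and 5.84 in rsl females. The 3' probe sets exceeded the 5' ones by 0.79 and 1.03 for Gapdh and 1.16 and 1.2 for actin in the rsl male pools, by 0.68 and 0.71 and by 1.06 and 0.95 in the wild type male pools, by 0.66 and 0.50 and by 1.09 and 0.95 in the rsl female pools, and by 0.72 and 0.59 and by 0.88 and 0.89 in the wild type female pools. Both values were higher in rsl than in wild type males, so a sign of RNA integrity moved with genotype there. In females the actin value was higher in rsl, while the Gapdh values of the strains overlapped and were not higher in rsl. Xist was high in every female pool and Ddx3y, Eif2s3y, Kdm5d and Uty were high in every male pool, as the labels require. The 2 pools of a group correlated at 0.998 in wild type females and 0.997 in rsl females across probe sets, with 5 and 28 probe sets at least 1 log2 unit apart. In wild type males the correlation was 0.988 with 528 such probe sets, and in rsl males 0.989 with 723, while wild type male 1 and rsl male 2 correlated at 0.991. Genes are not independent replicates in these correlations.

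**Figure D1:**
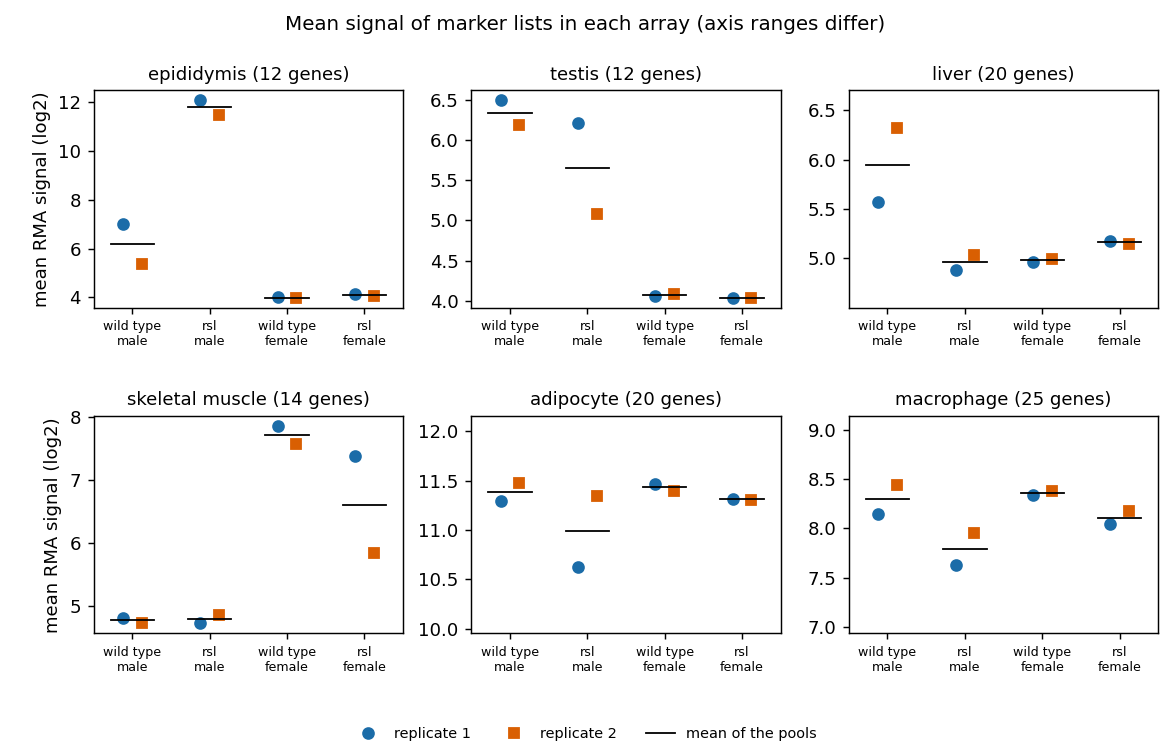
Mean RMA signal (log2, y axis) of 6 marker lists in each of the 8 arrays, by group on the x axis, with a circle for replicate 1, a square for replicate 2 and a line for the mean of the 2 pools. The epididymis list reaches 12.09 and 11.50 in rsl males and at most 4.16 in females.

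Averaged over sex, the rsl strain had less RNA of Rsl1, of 3 of the other 18 measured KRAB zinc finger genes of its cluster on chromosome 13 and of 4 tripartite motif genes on chromosome 7, and more of Zfp729a of the same cluster. This comparison asks what differs between the strains in fat of either sex. Effects of the Rsl genes and of segments of another strain cannot be told apart in it. Rsl1, measured by 1 probe set, was at least 2.11-fold lower (n = 4 against 4, limma adjusted p = 0.00573), with a mean of 4.99 ± 0.26 (SD, log2) in wild type and 3.77 ± 0.18 in rsl, which is near the background of the arrays. Zfp874a was at least 4.11-fold lower, Trim12a at least 4.70-fold and Trim30d at least 6.79-fold lower, and Trim34a and Trim30a changed by -2.62 ± 0.16 and -1.35 ± 0.11 (SE) on the log2 scale. Zfp729a rose by 1.03 ± 0.08. Trim12a has 3 probe sets, of which 1 passed the threshold. Erdr1, a gene of the pseudoautosomal region, rose 11.8-fold (3.56 ± 0.09, adjusted p = 2.65e-05), and Hddc3, a nucleotide hydrolase, rose 7.25-fold. Slc15a2, a peptide transporter, rose by 2.48 ± 0.19, and Mmd2, St6galnac5, Tpmt (thiopurine methyltransferase), Gpx6, Col6a4, Thumpd1 and Glrb rose by between 0.96 and 2.29. G530011O06Rik was at least 1.68-fold higher. Mest, an imprinted gene that tracks adipocyte growth, fell by 1.88 ± 0.13. The mast cell proteases Cma1 and Cpa3 changed by -1.63 ± 0.20 and -1.47 ± 0.15, and Prcp, Prxl2c, Fsd2 and Myo7a by between -1.58 and -1.38.

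In total 537 probe sets passed the threshold for the average, 153 higher and 384 lower in rsl, which are 101 genes higher and 212 lower. Without wild type female 1 and 2 it was 22 higher and 18 lower and 23 and 17, and without rsl female 1 and 2 it was 24 and 23 and 24 and 21, so the excess of falls was not kept there. The count was 1358 without wild type male 1, 182 without wild type male 2, 40 without either wild type female, 872 without rsl male 1, 6184 without rsl male 2, and 47 and 45 without rsl female 1 and 2. It was 229 on gene means, 1004 with array weights and 5128 without wild type male 1 and rsl male 1. Of the 31 genes named and called in the average, 17 lost their call without either wild type female, 18 and 17 without rsl female 1 and 2, 5 without wild type male 2 and 1 without wild type male 1 or rsl male 1.

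Genes called in both sexes in the same direction numbered 23, of which 9 were higher and 14 lower in rsl, as the dot plot of 8 of them shows. In males and females respectively, Erdr1 rose by 3.53 ± 0.13 and 3.59 ± 0.13, and Hddc3 by 2.70 ± 0.10 and 3.02 ± 0.10. Lcn2 rose by 2.02 ± 0.24 in males and was at least 10.9-fold higher in females. The others that rose were Slc15a2, St6galnac5, G530011O06Rik, Zfp729a, Thumpd1 and Cadps2, a regulator of vesicle exocytosis. Beside the zinc finger and tripartite motif genes, Mest, Prxl2c, Fsd2, Wfdc21, Adgre4, a receptor of myeloid cells, and 2700079J08Rik fell. Of the 23 genes, 7 lie on chromosome 7 and 6 on chromosome 13.

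**Figure D2:**
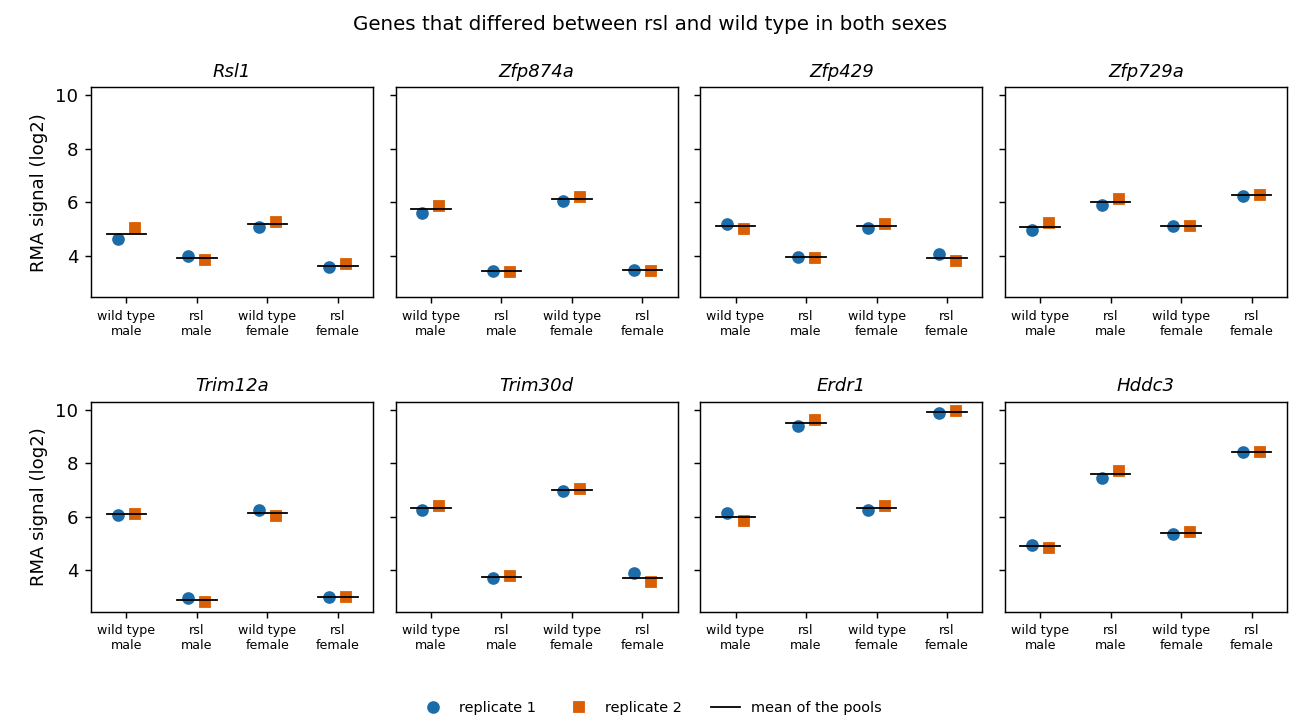
RMA signal (log2, y axis) of 8 genes that differed between the strains in both sexes, in each of the 8 arrays by group, with a circle for replicate 1, a square for replicate 2 and a line for the mean of the 2 pools. Rsl1 averages 4.82 and 5.17 in wild type males and females and 3.91 and 3.63 in rsl males and females.

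Among the 19 measured KRAB zinc finger genes of the Rsl cluster, Rsl1, Zfp874a, Zfp429 and Zfp708 fell and Zfp729a rose, in males, in females and in the average, and 14 did not pass the threshold. The list holds 29 genes, and 5 of the 19 lay more than 1 log2 unit above background in every female array. The lack of a call thus does not show that a gene was expressed and unchanged. Rsl1 fell by 0.91 ± 0.14 in males (adjusted p = 0.0407) and was at least 2.38-fold lower in females (adjusted p = 0.0181). Zfp874a was at least 3.66-fold lower in males and at least 4.62-fold lower in females. Zfp429 changed by -1.17 ± 0.11 and -1.19 ± 0.11, Zfp708 fell by 0.48 ± 0.08 in males and was at least 1.90-fold lower in females, and Zfp729a rose by 0.92 ± 0.11 and 1.13 ± 0.11. Rslcan18, the other named Rsl gene, changed by -0.34 ± 0.08 in males (adjusted p = 0.0888) and -0.04 ± 0.08 in females, at a level near background. Adjusted over the list alone, 7 genes were lower in males, 8 in females and 9 in the average, each beside 1 higher. Without any 1 of the female arrays the list held 0 higher and 1 lower gene in each sex and 0 higher and 2 or 3 lower in the average. Without wild type male 2 or rsl male 1 males had 2 lower genes, and without rsl male 2 the average had 6. The list was lower in camera (adjusted p = 0.00806 in males, 2.80e-06 in females and 0.000106 in the average). The adjusted p was 0.515, 0.198 and 0.172 with an estimated correlation and 0.0122, 0.00742 and 0.00129 with fry.

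Genotype calls were denser on 2 chromosomes. On chromosome 7 lay 41 of the 305 called genes with a chromosome, against 23.94 expected (odds ratio 1.85, 95% interval 1.29 to 2.59, Fisher's exact test, adjusted p = 0.0135), and on chromosome 13 lay 24 against 11.75 (odds ratio 2.17, 1.36 to 3.33, adjusted p = 0.0135). Chromosome 11 held 12 against 24.5 (odds ratio 0.465, adjusted p = 0.0386), and the other chromosomes did not pass. The adjusted p on chromosome 11 was 0.0748 without the listed zinc finger genes (odds ratio 0.472) and 0.476 with genes called in males or in females (odds ratio 0.743). In the order of measured genes of the assembly GRCm38.p6, the 100 genes from 2810408B13Rik to Pcsk1 on chromosome 13, which include the zinc finger cluster, held 10 called genes, 6 of them called in both sexes. The 100 genes from Map6 to 9130208D14Rik on chromosome 7 held 8, among them the 4 tripartite motif genes, and the 100 before them, from Zscan2 to Mogat2, also held 8. The 100 after them, from Gvin1 to Rexo5, held 7. Each other such stretch held 0 to 3 called genes on chromosome 7 and 0 to 4 on chromosome 13. Without the listed zinc finger genes the odds ratio on chromosome 13 was 1.76 (adjusted p = 0.125), and with genes called in males or in females it was 1.43 (adjusted p = 0.476).

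**Figure D3:**
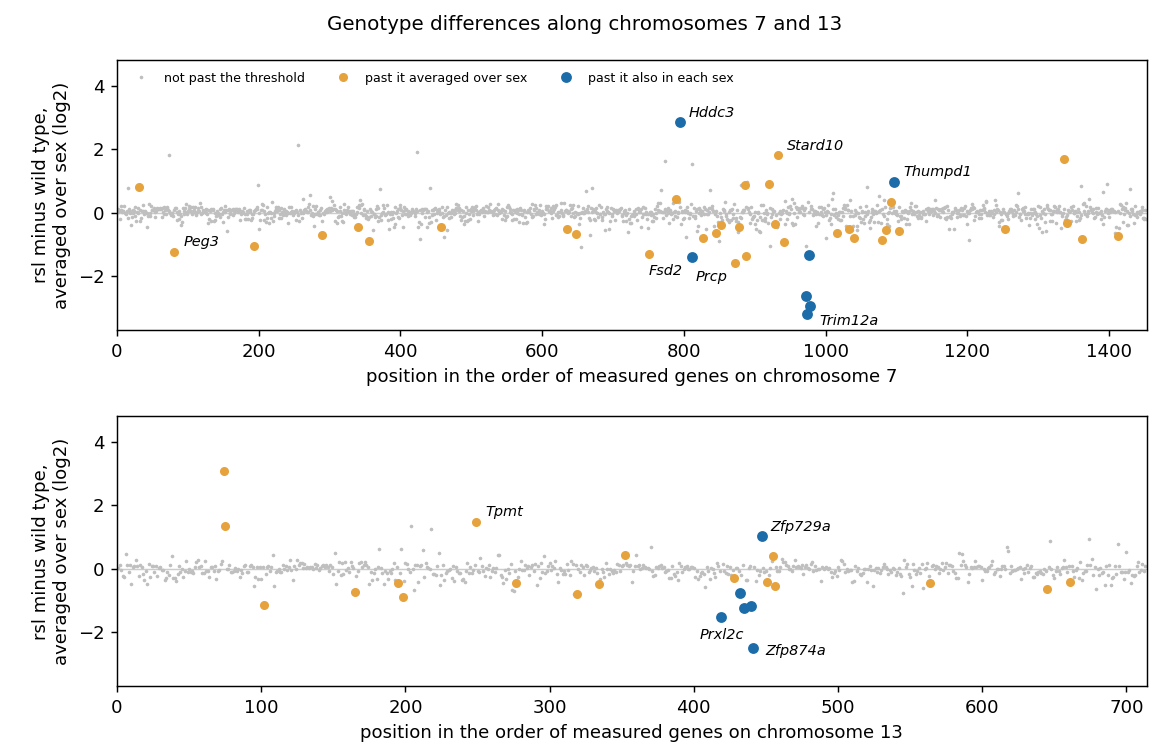
Genotype difference averaged over sex (rsl minus wild type, log2, y axis) of the measured genes of chromosomes 7 and 13 in their order along each chromosome (x axis), with genes past the threshold in orange and those also past it in each sex in blue. The blue points on chromosome 13 lie within the 100 genes from 2810408B13Rik to Pcsk1.

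Beside these genes, the average took in 7 of 12 epididymis genes and 2 of 25 macrophage genes. The Rsl targets known from liver (major urinary proteins, complement C4 and Cyp2d9) had 0 of 6 measured members past the threshold and 1 lower adjusted over the list alone. The list holds 16 members, and 2 of the 6 lay more than 1 log2 unit above background in every female array. The lack of calls thus says little about the rest. Of 25 macrophage genes, Ccr2 fell by 0.90 ± 0.11 and Cd84 fell by 0.49 ± 0.08, and 18 were lower adjusted over the list alone. Among 12 endothelial genes 0 passed and 6 were lower adjusted over the list alone, and among 22 matrix genes 0 passed and 6 were lower in the same way. The camera test placed these 3 lists lower (adjusted p = 3.73e-11, 3.26e-05 and 0.000126), with an adjusted p of 0.770 for each under an estimated correlation. Camera also called the adipocyte, adipokine, testis, mesothelium, muscle and liver lists lower and the ovary and mammary epithelium lists higher, with 1 ovary gene higher and 1 lower past the threshold (adjusted p from 0.00831 to 0.0362), with an adjusted p from 0.442 to 0.92 under an estimated correlation. The macrophage, endothelial and matrix lists were lowest in rsl male 1, the pool with the lowest adipocyte mean. The macrophage count was 7 without wild type male 1, 1 without rsl male 1, 18 without rsl male 2 and 0 without any other array. Of the 12 epididymis genes 7 rose, 12 without wild type male 1 and 3 without any 1 of the female arrays (camera adjusted p = 3.73e-11, 0.104 with an estimated correlation). Sfrp5, a Wnt antagonist secreted by adipocytes, fell by 1.08 ± 0.11, and Fkbp5, a glucocorticoid-induced chaperone, rose by 1.00 ± 0.14.

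In males, rsl pools held far more RNA of epididymal secretory genes than wild type pools. Lypd8 rose by 8.30 ± 0.25 (315-fold, n = 2 against 2, adjusted p = 6.77e-05), Lcn8, a lipocalin of the epididymis, by 7.87 ± 0.47, and Cst11, an epididymal cystatin, was at least 200.7-fold higher. Rnase10, Pate5, Cst12, Lcn9, Cst8, Cstdc2, Slc38a5 and Pate6 rose by between 6.27 and 7.64, and Adam28 was at least 75.1-fold higher. Of the 12 epididymis genes 7 rose, or 9 adjusted over the list alone, and none fell (camera adjusted p = 3.00e-14, 0.0624 with an estimated correlation). Wild type male 1 held 4 further members near the rsl level, with Crisp1 at 12.60, Lcn5 at 12.59, Adam7 at 11.04 and Wfdc15b at 11.27, and without that pool all 12 rose. Without any 1 of the female arrays 6 rose.

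Some genes of the liver, testis, macrophage and clock lists were lower in rsl males. Serpina1c changed by -3.53 ± 0.50, Ttr by -3.21 ± 0.45 and Alb by -2.76 ± 0.43, and Ttr and Alb are the 2 of 20 liver genes that fell, with 10 lower adjusted over the list alone. Wild type male 2 had the highest liver list mean, 6.32, against 5.57 in wild type male 1 and 4.89 and 5.04 in rsl males. Akap3, Ldhc and Spata4, which belong to sperm, changed by -2.56 ± 0.37, -2.15 ± 0.36 and -2.08 ± 0.32, and Ldhc was the 1 of 12 testis genes that fell. Mtarc1, a mitochondrial amidoxime reductase, changed by -2.27 ± 0.19, Cma1 by -1.80 ± 0.28 and Ccr2 by -1.13 ± 0.16, the 1 of 25 macrophage genes that fell, with 16 lower adjusted over the list alone. Trim12a was at least 4.69-fold lower, Trim30d at least 5.55-fold lower and Trim34a fell by 2.48 ± 0.23. Of 17 clock genes Per3, Nr1d2 and Dbp fell, with changes of -1.03 ± 0.14, -0.61 ± 0.09 and -0.97 ± 0.11. Egr2 rose by 3.86 ± 0.57, and Sfrp5, Sult1e1 and Muc16 changed by between -1.69 and -0.96. The liver, testis, macrophage and clock lists were lower in camera (adjusted p = 0.000366, 0.00880, 1.67e-09 and 0.00806), with an adjusted p of 0.735 for each under an estimated correlation. Camera also called the adipocyte, fatty acid oxidation, oxidative phosphorylation, endothelial, matrix and adipokine lists lower and the cholesterol synthesis, ovary and mammary epithelium lists higher in males (adjusted p from 0.000226 to 0.0437), although the 1 cholesterol synthesis gene and the 1 ovary gene past the threshold were lower, with an adjusted p from 0.560 to 0.766 under an estimated correlation. Of the liver genes 10 were lower without wild type male 1, 4 without wild type male 2 and 5 without rsl male 2. Of the clock genes 5 were lower without wild type male 1, 1 without rsl male 1 and 8 without rsl male 2. Of the testis genes 5 and 4 were lower without rsl male 1 and 2, and of the macrophage genes 5 and 16 without wild type male 1 and rsl male 2. Without any 1 of the female arrays limma called 0 of these 4 lists, as it did for the clock and macrophage lists without wild type male 2 and for the liver and macrophage lists without rsl male 1, while 9287 probe sets had an unadjusted p under 0.05 with all arrays.

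In males 594 probe sets passed, 221 higher and 373 lower in rsl (146 and 221 genes). In the simulation the threshold let through too many false calls in males, whose pools varied more than the shared spread. Female arrays enter the male contrast only through that shared spread. Falls did not exceed rises without either wild type female (26 higher, 18 lower), either rsl female (20 and 11) or rsl male 1 (239 and 233), and array weights gave 146 and 154. A limma fit of the male arrays alone called 0, with 5523 at an unadjusted p under 0.05, and the replicate block called 1034. The count was 1420 without wild type male 1, 113 without wild type male 2, 44 without either wild type female, 472 without rsl male 1, 6985 without rsl male 2 and 31 without either rsl female. It was 310 on gene means, 300 with array weights, 3843 without wild type male 1 and rsl male 1, and 1213 without genes at least 1 log2 unit apart between the pools of a male group. Of the 50 genes named and called in males, 29 lost their call without either wild type female, 31 without either rsl female, 2 and 20 without wild type male 1 and 2, and 14 without rsl male 1.

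In females, rsl pools had more RNA of Lcn2 and Sprr2f and less of Mest, Peg3 and H19. Lcn2, the secreted lipocalin 2, was at least 10.9-fold higher (adjusted p = 0.00361, n = 2 against 2), and Sprr2f, a cornified envelope gene, at least 9.63-fold higher. Mmd2, Prap1, Stard10, a lipid transfer protein, Slc15a2, St6galnac5, Usp2 and Aqp11, an aquaporin, rose by between 2.00 and 3.67, and G530011O06Rik was at least 2.18-fold higher. Mest, Peg3 and H19, which are imprinted, changed by -2.07 ± 0.18, -1.92 ± 0.16 and -1.48 ± 0.18. Trim30d changed by -3.29 ± 0.12, Trim34a by -2.76 ± 0.23 and Trim30a by -1.49 ± 0.16, Trim12a was at least 4.70-fold lower, Fsd2 and Prxl2c changed by -1.60 ± 0.08 and -1.52 ± 0.11, and Esm1, an endothelial proteoglycan, fell by 1.498 ± 0.158. Of 17 clock genes Ciart and Hlf rose, by 1.84 ± 0.15 and 1.04 ± 0.13, and Dio2, the deiodinase that activates thyroid hormone, rose by 1.59 ± 0.19. Fkbp5 rose by 1.63 ± 0.20. Dio2 was not called without any 1 of the wild type arrays or rsl female 1, and Fkbp5 not without any 1 of the wild type or rsl female arrays. The clock list was higher in camera (adjusted p = 0.000250, 0.693 with an estimated correlation), with 8 higher and 2 lower adjusted over the list alone. Without any 1 of the female arrays 0 clock genes passed in limma, against 4952 probe sets at an unadjusted p under 0.05 with all arrays, and without either rsl male 3 were higher and 2 lower. Of 14 muscle genes, 25 macrophage genes, 22 matrix genes, 11 mesothelium genes and 43 oxidative phosphorylation genes 0 passed in females. The camera test placed the muscle, macrophage, matrix and mesothelium lists lower (adjusted p = 6.15e-07, 6.15e-07, 4.88e-06 and 7.97e-05) and oxidative phosphorylation higher (2.80e-06), with an adjusted p of 0.239 for mesothelium and 0.693 for the others under an estimated correlation. It also placed the endothelial, interferon and early response lists lower and lipogenesis higher (adjusted p from 0.00168 to 0.0198, and 0.693 for each under an estimated correlation). Rsl female 2 had the lower muscle mean of the rsl females, and without rsl female 1 3 muscle genes were lower.

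In females 94 probe sets passed, 52 higher and 42 lower in rsl (33 and 23 genes). Falls exceeded rises in the fit of the female arrays alone (587 higher, 1422 lower), with array weights (162 and 367), without either rsl male (134 and 326), without either wild type male (52 and 53), without wild type female 1 (4 and 5) and with the replicate block (34 and 37). The count was 9 and 10 without wild type female 1 and 2, 18 and 15 without rsl female 1 and 2, and 460 without either rsl male. It was 2009 in a fit of the female arrays alone, 48 on gene means and 529 with array weights, and the replicate block gave 71. Of the 36 genes named and called in females, 28 lost their call without either wild type female, 25 and 26 without rsl female 1 and 2, and 3 without either wild type male.

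The interaction asks whether the genotype difference depended on sex, and 26 probe sets passed it, 14 higher and 12 lower in males (13 and 8 genes). The rise in rsl males exceeded that in females for Lypd8 (adjusted p = 0.00110), Lcn8, by 7.76 ± 0.67, Cst11, Rnase10, Lcn9, Cst12, Pate5, Cstdc2, Cst8, Slc38a5, Adam28 and Teddm2. The reverse held for Sprr2f, Prap1, Crtac1, the clock genes Ciart and Dbp, and Pcsk4, Nrg4, an adipokine, and Slc25a33. Of these genes Lypd8, Cst11, Cst12, Pate5, Slc38a5, Adam28, Teddm2 and Sprr2f lay at or below background in every array of at least 1 group, so no size is given for them here. Of the epididymis list 6 members passed, or 8 adjusted over the list alone, with camera adjusted p of 5.75e-17 and 0.0448 with an estimated correlation. The count of 26 was 317 without wild type male 1, 4 without either wild type female, 203 without rsl male 1, 2860 without rsl male 2, and 5 and 6 without rsl female 1 and 2. It was 41 with an intensity trend, 76 with array weights and 2117 without wild type male 1 and rsl male 1. The balance turned without wild type male 2 (16 higher, 23 lower), without rsl male 2 (1156 and 1704) and without wild type male 1 and rsl male 1 together (1049 and 1068). Without wild type male 1 all 12 members of the list passed, and without any 1 of the female arrays 1 did. The 2 clock genes became 6 without wild type male 1, 9 without rsl male 2 and 0 without any 1 of the female arrays. Of the 21 genes that passed, 17 lost their call without either wild type female, 16 without either rsl female and 4 without wild type male 2.

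The genotype differences of the sexes correlated at r = 0.262 (Spearman 0.286) across 45037 probe sets, which are not independent replicates. They shared 13 probe sets higher in both sexes against 0.255 by chance and 24 lower in both against 0.348, with 3 called in opposite directions.

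**Figure D4:**
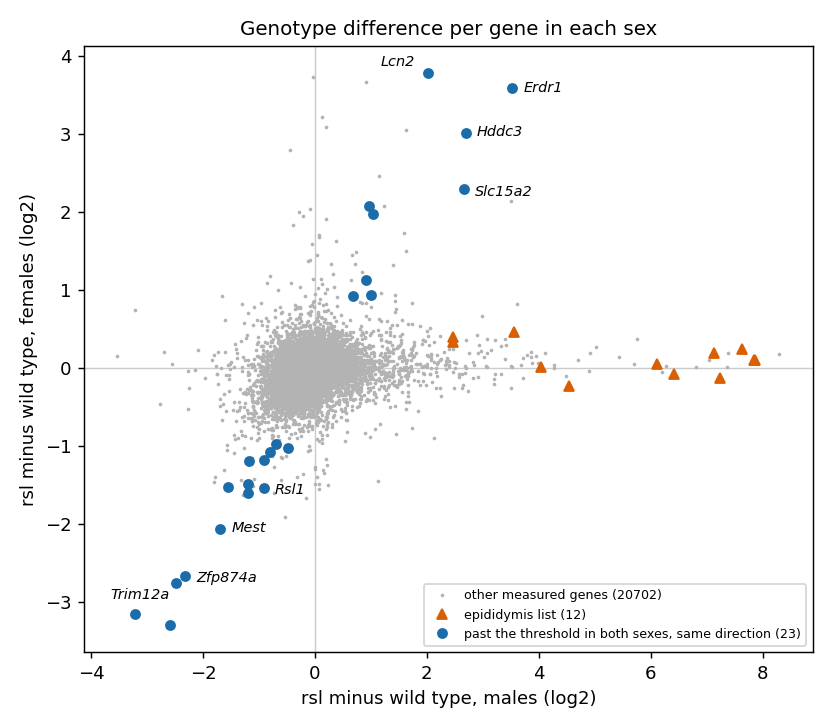
Genotype difference of each measured gene in males (x axis) and in females (y axis), both rsl minus wild type on the log2 scale, with the 12 epididymis genes as triangles and the 23 genes called in both sexes in the same direction as circles. The triangles extend along the male axis, and the circles lie in the lower left and upper right.

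Some lipid synthesis genes and most listed skeletal muscle genes had less RNA in wild type males than in wild type females. Muscle, testis and positional genes differed with sex too, so an effect of sex on fat cannot be told apart from the tissue taken. Of 24 lipogenesis genes 9 were lower, or 14 adjusted over the list alone, among them Elovl6, which elongates fatty acids, by -3.36 ± 0.40, Acss2 by -1.98 ± 0.22, Acly (ATP citrate lyase) by -1.73 ± 0.16 and Acaca (acetyl-CoA carboxylase) by -1.69 ± 0.21. Of 25 cholesterol synthesis genes 3 were lower, among them Lss and Dhcr7, and of 43 oxidative phosphorylation genes 0 passed. No fatty acid oxidation or epididymis gene passed. Of 14 thermogenic genes Cidea, Cox8b, Kcnk3, Ucp1, Cox7a1 and Otop1 were lower, Cidea by -2.30 ± 0.24 and Cox8b by -2.45 ± 0.23, while Gk (glycerol kinase) and Slc27a2 (a fatty acid transporter) were 2.46 ± 0.31 and 2.95 ± 0.41 higher. Of 14 skeletal muscle genes 10 were lower, with Tnnc2 differing by -4.83 ± 0.59, Acta1 by -4.41 ± 0.67 and Myh1 by -4.12 ± 0.52, and Myh4 and Tnnt3 at least 18.4-fold and 9.42-fold lower. Mylpf differed by -3.43 ± 0.41. Cuzd1 was 6.77 ± 0.83 higher, Lcn2 at least 75.8-fold higher, Kcnk1 at least 32.5-fold and Plet1 at least 25.7-fold higher. Sult1e1, the estrogen sulfotransferase, was 5.52 ± 0.17 higher, and Prom1, Calml3, Rnf128, Mmp7 and Gstm7 were 4.50 to 5.25 higher. Pcp4, Akr1c14, a hydroxysteroid dehydrogenase, Cybrd1 and Hoxa10 were lower by a log2 difference of between -5.13 and -3.20.

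Other tissue and signalling lists also differed in wild type. Of 12 testis genes 7 were higher, with Prm2 (protamine 2) 4.11 ± 0.64 higher and Tnp1 at least 10.9-fold higher, and of 20 liver genes Ttr, Apoa1, Serpina1b and Fga were higher. Of 11 mesothelium genes 6 were lower, among them Wt1 by -1.78 ± 0.17 and Msln by -1.21 ± 0.10, and the keratins Krt8 and Krt18 were 2.01 ± 0.32 and 2.52 ± 0.46 higher. Of 22 matrix genes Postn, Lum, Col6a1 and Col6a2 were lower, and of 21 interferon response genes 5 were lower, Ifi44 by -1.15 ± 0.11. Among 17 positional genes Hoxc10 and Hoxa9 differed by -3.14 ± 0.19 and -2.90 ± 0.25, Shox2 was lower, and Hoxc8 was 1.07 ± 0.18 higher. Fkbp5 was 2.26 ± 0.20 higher and Hsd11b1, which regenerates active glucocorticoid, 1.64 ± 0.23 higher. Of 6 genes that escape X inactivation Kdm6a and Eif2s3x were lower, by -0.61 ± 0.07 and -0.60 ± 0.07. Camera called the lipogenesis, cholesterol synthesis, fatty acid oxidation, oxidative phosphorylation, muscle, thermogenic, mesothelium, matrix, interferon and X escape lists lower and the testis, liver and epididymis lists higher (adjusted p from 4.02e-12 to 0.0167), with an adjusted p from 0.119 to 0.805 under an estimated correlation.

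In wild type 1725 probe sets passed for sex, 727 higher and 998 lower in males (505 and 578 genes). The balance turned without wild type male 1 (661 higher, 409 lower), without wild type male 2 (773 and 670) and without wild type male 1 and rsl male 1 (2424 and 1941). The count was 1070 without wild type male 1, 205 and 149 without wild type female 1 and 2, 3652 without either rsl male and 693 without either rsl female. It was 1033 on gene means, where the main fit called 1083 genes, and 3365 with array weights. Of the 66 genes named and called here, 43 and 49 lost their call without wild type female 1 and 2, 15 and 13 without wild type male 1 and 2, and 15 without either rsl female. The count of lipogenesis genes was 6 without wild type male 2 or either rsl female, 1 and 0 without wild type female 1 and 2, and 14 without either rsl male. That of muscle genes was 4 without either wild type male and 0 without either wild type female. That of testis genes was 3 without wild type male 1, 0 without either wild type female and 2 without either rsl female. The matrix count of 4 and the interferon count of 5 were 2 without either wild type male or either rsl female, and 10 and 8 without either rsl male. Without wild type female 1 and 2 the counts of lower genes were 3 and 1 for mesothelium and 1 and 1 for the matrix, and 0 for the thermogenic, interferon and X escape lists, while the liver count was 0. Without wild type male 1 the thermogenic list had 3 lower genes and the liver list 8 higher ones, and without either rsl female the liver list had 1.

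In rsl mice members of the lipid, thermogenic, oxidative phosphorylation, clock and epididymis lists passed the threshold for sex. Here too, sex and the tissue taken cannot be told apart. Of 24 lipogenesis genes 20 were lower in males, or 21 adjusted over the list alone, with Me1 (malic enzyme) differing by -2.28 ± 0.27, Acss2 by -1.89 ± 0.22, Acaca by -1.86 ± 0.21 and Fasn (fatty acid synthase) by -1.12 ± 0.26. Of 21 lipolysis and fatty acid oxidation genes 10 were lower, among them Acadl and Abhd5, and Cpt1a was higher. Of 43 oxidative phosphorylation genes 19 were lower, or 33 adjusted over the list alone, with Ndufs1 at -0.89 ± 0.15 and Uqcrfs1 at -0.78 ± 0.11. Of 14 thermogenic genes Cidea, Cox8b, Elovl3, Kcnk3, Dio2 and Cox7a1 were lower, Cidea by -2.56 ± 0.24, and Gk and Slc27a2 were higher. Of 17 clock genes 9 were lower, among them Ciart by -1.85 ± 0.15, Per2 by -1.65 ± 0.25 and Dbp by -1.48 ± 0.11, and Arntl, whose protein drives the clock, was 0.85 ± 0.18 higher. All 12 epididymis genes were higher, Crisp1 at least 341-fold, Lcn5 by 8.50 ± 1.76, Lcn8 by 8.48 ± 0.47, Adam7 by 8.03 ± 1.55 and Lcn9 by 7.95 ± 0.42. Defb42, Cuzd1 and Lypd8 were 8.33 to 8.60 higher, and Ceacam10, Slc38a5, Muc15 and C4bp were at least 138-fold, 237-fold, 184-fold and 143-fold higher. Pparg, Slc2a4 and Adig, the 3 of 20 adipocyte genes that passed, were lower by -1.30 ± 0.23, -0.86 ± 0.19 and -0.80 ± 0.20, and rsl male 1 had the lowest mean of that list. The median over the adipocyte list was -0.263 with all arrays and -0.053 without rsl male 1.

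Further genes told the sexes of the rsl strain apart. Pcp4, Nrn1, Cybrd1, Mtarc1, Tnnc2, Ptger3, a prostaglandin receptor, Myh1, Hoxc10 and AI844685 were lower in males by a log2 difference of between -4.90 and -3.01, and Akr1c14 and Sprr2f were at least 11.7-fold and 9.56-fold lower. Of 11 mesothelium genes 7 were lower, Muc16 by -1.92 ± 0.16, and Krt8 and Krt18 were higher. Of 22 matrix genes 9 were lower, Lum by -1.48 ± 0.18 and Fn1 (fibronectin) by -1.31 ± 0.22, and of 14 muscle genes 4 were lower. Of 12 testis genes 5 were higher and Star was lower. Of the 23 genes of steroid metabolism and receptors, Greb1, Hsd11b1 and Fkbp5 were among those higher, Greb1 by 3.37 ± 0.52, and Akr1c14, Esr1, Hsd17b12 and Hsd11b2 were lower. Of 17 early response genes 3 were lower, and Egr2 was the 1 that was higher, by 4.74 ± 0.57. Of 6 liver Rsl targets 2 were lower in males, or 3 lower and 1 higher adjusted over the list alone, with Mup3 at least 5.01-fold lower, and camera did not call the list (adjusted p = 0.423). Camera called the lipogenesis, fatty acid oxidation, oxidative phosphorylation, thermogenic, clock, adipocyte, mesothelium, matrix, muscle, macrophage, interferon and X escape lists lower and the epididymis and testis lists higher (adjusted p from 1.60e-14 to 0.0276), with an adjusted p from 0.0602 to 0.782 under an estimated correlation.

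In rsl 5559 probe sets passed for sex, 2131 higher and 3428 lower in males (1345 and 1897 genes). The count was 2709 without either wild type female, 3241 without rsl male 1, 10015 without rsl male 2, 716 and 574 without rsl female 1 and 2, 1862 in a fit of the rsl arrays alone and 3248 on gene means. Without rsl female 1 or 2, the counts of lower genes were 3 and 2 for lipogenesis, 0 and 0 for oxidative phosphorylation and 3 and 2 for the clock. The oxidative phosphorylation count was 7 without either wild type female and 6 without rsl male 1, the clock count 6 without rsl male 1, the lipogenesis count 13 without either wild type female, and the epididymis count 7 without either rsl female. Fatty acid oxidation had 3 lower genes without either wild type female, 6 and 18 without rsl male 1 and 2 and 0 without either rsl female, and the adipocyte list had 1, 3, 14 and 0 in the same order. The matrix list had 4, 6, 15 and 1. Without either rsl female the mesothelium list had 4 lower genes, the testis list 0 higher and the thermogenic list 0 higher genes, and the muscle list had 2 and 10 lower genes without rsl female 1 and 2. The testis list had 8 higher genes without rsl male 2. The steroid list, with 4 higher and 4 lower genes, had 2 and 4 without either wild type female, 4 and 8 without rsl male 2, and 0 and 2 or 0 and 1 without rsl female 1 or 2. Egr2 and Mup3 were not called without either rsl female. Of the 74 genes named and called here, 47 and 48 lost their call without rsl female 1 and 2, 17 without either wild type female, 13 without rsl male 1 and 1 without either wild type male.

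**Figure D5:**
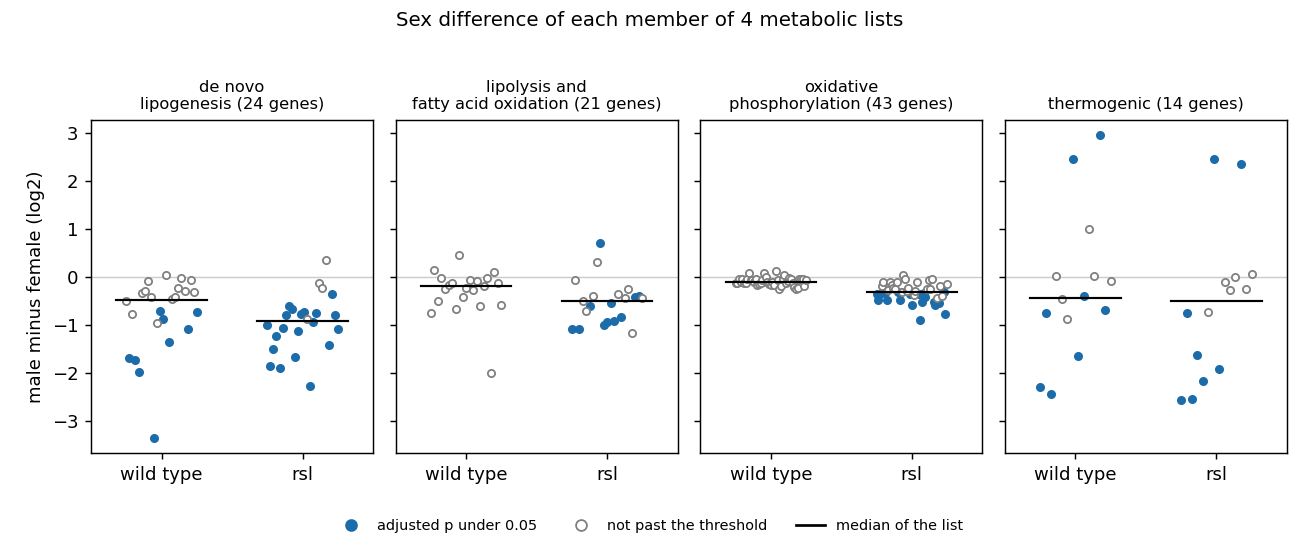
Male minus female difference (log2, y axis) of each member of 4 metabolic lists in wild type and in rsl mice (x axis), with filled points for genes past the threshold and a line for the median of the list. The lipogenesis medians are -0.48 in wild type and -0.92 in rsl.

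The sex differences of the strains correlated at r = 0.720 (Spearman 0.534) across probe sets, or 0.524 without wild type male 1. They shared 355 probe sets higher in males against 34.4 by chance and 688 lower against 76.0, with 9 called in opposite directions. Whether a list's sex difference itself differed between the strains is what the interaction tests, and for lipogenesis and oxidative phosphorylation its camera adjusted p was 0.0273 and 4.95e-08, with 0 members past the threshold in each, and 0.693 under an estimated correlation for both.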

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

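The tests of epididymal transcripts, of rises on chromosomes 7 and 13 and of segments of another strain were chosen after the results were seen, and those of falls on these chromosomes and of collection times before. The genotype difference in males differed from that in females for 21 genes and 11 gene lists by the interaction test, and these are given here as fitted male minus female values on the log2 scale. For Lypd8, Cst11, Cst12, Pate5, Slc38a5, Adam28, Teddm2 and Sprr2f at least 1 group lay at or below background in every array, so their values do not measure the size of the difference or rank it, and neither does the epididymis median below. It was higher in males for Lypd8 (8.12), Lcn8 (7.76), Cst11 (7.74), Rnase10 (7.39), Lcn9 (7.35), Cst12 (7.35), Pate5 (7.19), Cstdc2 (6.94), Cst8 (6.94), Slc38a5 (6.79), Adam28 (6.49) and Teddm2 (5.39), and for Tm7sf3 (1.06), which lies outside the naming rule and was chosen after its value was seen. It was lower in males for Slc25a33 (-1.10), Nrg4 (-1.40), Pcsk4 (-1.47), Dbp (-1.81), Crtac1 (-2.22), Ciart (-2.23), Prap1 (-3.09) and Sprr2f (-3.78).

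The list medians of the same difference were 6.27 for epididymis (camera adjusted p = 5.75e-17), 1.19 for skeletal muscle (0.000428) and 0.33 for early response genes (0.0477). They were -0.21 for adipocytes (0.0433), -0.31 for lipogenesis (0.0273), -0.29 for lipolysis and fatty acid oxidation (0.00671), -0.22 for oxidative phosphorylation (4.95e-08) and -0.27 for macrophages (0.00895). They were -0.48 for testis (0.0377), -0.52 for liver (7.08e-06) and -0.48 for the clock (1.84e-05). With an estimated correlation the adjusted p was 0.0448 for epididymis and 0.693 or 0.708 for the others.

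Epididymal transcripts were high in both rsl male pools, low in females and uneven between the wild type male pools, with signals for Gpx5 and Lcn5 of 13.088 and 13.017 in rsl male 1 and of 12.943 and 12.708 in rsl male 2. The same genotype effect in both sexes is argued against by a female median of 0.109 with a spread of 0.211 over members. Epididymal tissue in the pooled fat of rsl males stays open, since all 12 of 12 measured members lay above every female array in both rsl male pools, which a genotype effect in males would also give. Of the 12, 1 lay more than 1 log2 unit above background in every female array. A genotype effect confined to males stays open too. The bound set against it was more than 1 of 12 members that a wild type male pool holds within 1 log2 unit of an rsl male pool or above it. It was passed by 4 (Crisp1, Lcn5, Adam7 and Wfdc15b), but these rest on wild type male 1 alone. In these 4 the wild type male pools differ by 5.465 to 6.547, a difference between pools of the same genotype. For the other 8 members the wild type male pools differ by a median of 1.314 with a spread of 1.096. For the difference between rsl and wild type males, dissection and genotype cannot be told apart for any of the 12.

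Genotype calls were in excess on chromosomes 7 and 13 (41 and 24 called genes, Fisher's exact test, adjusted p = 0.0135 for each), with 50 falls against 24.22 by chance and 15 rises against 11.47. Sequence variants under the probes were tested in the 13 falls with another bright probe set. In 12 of them (92.31%, exact binomial interval 63.97% to 99.81%) another probe set also fell by a set part of the called fall. This passed the value set against such variants. No p-value was asked of the second fall and no chance rate was taken, so it does not exclude them. The other 38 falls stay open, since an excess in falls is what such variants would give. The 15 rises passed the bound of 5 set against such variants, but that bound was wrong because chance alone exceeds it, so their count decides nothing. Since such variants would give falls, the direction of these rises goes against them. Whether the wild type strain matches the probes better was not tested. Segments of another strain carried with the rsl alleles may contribute, but the odds ratio of 2.171 on chromosome 13 lies between the values set for and against this. That ratio covers a whole chromosome, so it cannot judge a shorter segment. The called genes were denser in 1 stretch of 100 genes on chromosome 13 and in adjoining stretches on chromosome 7. The strain that gave the rsl alleles was not analysed here, so segment and Rsl effects cannot be told apart.

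Of 17 clock genes 2, Dbp and Ciart, passed the interaction in limma. The genotype difference of Dbp was -0.97 ± 0.11 in males (adjusted p = 0.0186) and 0.84 ± 0.11 in females (adjusted p = 0.0502, not past the threshold). Different times of tissue collection between groups could give this, and would move both Arntl and Npas2 against Dbp, by more than 0.5, while values within 0.2 of 0 were set against it. The interaction difference of Arntl was 1.48 ± 0.25 in that direction (adjusted p = 0.136), and that of Npas2 was 0.069 ± 0.098, within 0.2 of 0. That bound was wrong for Npas2, whose signals of 4.12 to 4.37 lie near the background of 3.73 to 4.01, where a change would hardly show. Collection times are not given in the sources used here, so time and group cannot be told apart, and an effect of genotype on the clock that depends on sex stays open, untested.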

How the results depend on the processing

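The fits without wild type male 1 and rsl male 1, the fit without genes that differ between pools of a male group, and the chromosome test on genes called in both sexes were tests chosen after the data were seen. Arrays have no depth, and signal over background limits what is read: 62.85% to 70.96% of probe sets lay above background, and below it only bounds are given. The other deposited table was not run, because its headings match no sample. With 1 array left out, the lone sample of its group is assumed to vary like the other groups. An array left out of a group that a contrast does not compare leaves the differences of that contrast unchanged. Its count then moves only through the shared spread and the degrees of freedom. Where no other reason is given below, the cause was not tested.

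Quantile normalization, median centring and the brighter probe sets kept all 6 counts within 1.5 times. Scaling moved the median of all probe sets by at most 0.029. Quantile normalization turned the sign of 10 of 180 list medians and median centring that of 8, with main medians of at most 0.035 and 0.014.

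A fit of only the 2 groups compared called 0 in males (5523 at an unadjusted p under 0.05, limma), 2009 in females and 1862 for sex in rsl. The replicate block called 1034 in males. Gene means, which test fewer units, called 310 in males, 48 in females, 229 averaged, 1033 for sex in wild type and 3248 in rsl. Counted in genes, the main fit called 367, 56, 313, 1083 and 3242 in the same order. Array weights called 300 in males, 529 in females, 1004 averaged, 3365 for sex in wild type and 76 for the interaction, and the intensity trend 41 for the interaction.

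Without wild type male 1 and rsl male 1 the counts were 3843 in males, 5128 averaged, 4365 for sex in wild type and 2117 for the interaction. Without genes at least 1 log2 unit apart between pools of a male group the count in males was 1213.

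With each array left out in turn, the counts ran from 31 to 6985 in males, 9 to 460 in females, 40 to 6184 averaged, 149 to 3652 for sex in wild type, 574 to 10015 for sex in rsl and 4 to 2860 for the interaction. The correlation of genotype effects ran from 0.233 to 0.257, and that of sex effects from 0.524 to 0.784.

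Of 180 list tests 79 passed in camera, 1 with an estimated correlation and 27 in fry, 24 of them shared with the 79. The odds ratio on chromosome 13 of 2.171 was 1.426 for genes called in males or in females (adjusted p = 0.476) and 1.755 without the listed zinc finger genes (adjusted p = 0.125), against 9.43 for genes called in both sexes (adjusted p = 0.00295), so its adjusted p ran from 0.00295 to 0.476. The lower odds ratio on chromosome 11 lost its call in each of these 3 settings (adjusted p from 0.0748 to 1).

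The 278 results of named genes gave 4647 values over these settings, of which 3786 kept their direction and their side of the threshold and 861 kept the direction but fell short of the threshold. None reversed.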

Other observations

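Pgr and Agt differed between the sexes in both strains. The progesterone receptor Pgr differed between males and females by -2.58 ± 0.20 in wild type and -2.53 ± 0.20 in rsl, and Agt, which codes for angiotensinogen, was 1.52 ± 0.24 and 1.31 ± 0.24 higher in males. Sfrp5 was 1.25 ± 0.16 higher in wild type males, and Hoxd8 and Gpc4 were 1.31 ± 0.24 and 0.71 ± 0.11 higher in rsl males. Agt was not called in wild type without wild type male 2 or any 1 of the female arrays, and Sfrp5 not without either wild type female. Without either rsl female Agt, Hoxd8, Gpc4 and Srebf2 were not called in rsl, nor was Hoxd8 without either wild type female. Srebf2 of cholesterol synthesis was 0.58 ± 0.07 higher in rsl males. Of the 25 cholesterol synthesis genes 2 were higher and 6 lower in rsl males. These counts were 5 and 5 without rsl male 2, 0 and 1 without either rsl female, and 2 and 4 without either wild type female. Of 16 ovary, uterus and oviduct genes 3 were higher and 3 lower in rsl males, against 1 and 3 without either wild type female, 2 and 3 without rsl male 1, and 1 and 2 without either rsl female.

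Several immune and blood genes also differed between the sexes. In wild type the B cell gene Ighm was 0.92 ± 0.19 higher in males, the T cell gene Thy1 differed by -0.54 ± 0.08 and the erythroid gene Ahsp by -1.59 ± 0.26. Ighm and Thy1 were not called without any 1 of the wild type arrays, Ighm not without either rsl female, and Ahsp not without wild type male 2, wild type female 2 or either rsl female. In rsl the macrophage gene Cd163 differed by -1.18 ± 0.24, Blnk by 1.46 ± 0.20 and Jchain by -1.98 ± 0.38. Krt5 and Epcam of 10 mammary epithelium genes were 1.39 ± 0.24 and 0.72 ± 0.18 higher, and Emcn of 12 endothelial genes differed by -0.77 ± 0.20. Of 25 macrophage genes 4 were lower in rsl males, and of 21 interferon genes 3. Without rsl male 2 these counts and the endothelial count of 1 were 10, 12 and 9, and without either wild type female 1, 1 and 0. Without rsl male 1 the interferon and endothelial counts were 0 in limma, with 9811 probe sets at an unadjusted p under 0.05. Without rsl female 1 or 2 the counts of macrophage, interferon, endothelial and mammary genes were 0 in limma, with 9699 and 9030 probe sets at an unadjusted p under 0.05. The B cell list, with 3 higher and 2 lower genes, had 2 and 0 without either wild type female, 2 and 1 without rsl male 1, 3 and 4 without rsl male 2 and 0 and 0 without either rsl female. The mammary count of 2 was 1 without rsl male 1 or either wild type female. No pancreas gene of 11 passed in any of the 6 contrasts.

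The genotype split was compared with other splits of the 8 arrays into 4 and 4, with sex as a covariate, in a test chosen in advance and limited to 18 splits after its result was seen. Of the 18 splits with 2 males and 2 females on each side 1, the real one, gave as many called probe sets, with 196 calls in limma against 0 for the highest other split, where the model with 4 groups calls 537. These splits are too few for a share under 0.05.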
